A study of Mus musculus with 4 samples.

How the data were processed

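RNA polymerase II (Pol II) was measured by chromatin immunoprecipitation and sequencing in E14Tg2A cells, a line of mouse embryonic stem cells, per the labels. The cells had received lentivirus carrying a non-targeting short hairpin RNA (NT) or a hairpin against Lsd1 (shLsd1), the histone demethylase also called Kdm1a. The groups held 1 NT library, 2 shLsd1 libraries and 1 input library of NT cells. Virus was harvested at 48 h, and cells were fixed in 1% formaldehyde for 10 min, per the labels' protocols. Chromatin was sheared to 300 to 500 bp and libraries were amplified over 13 cycles, per the labels' protocols.

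The deposited values were positions of aligned reads, 1 line per read, and carried no normalization. The submitters' processing notes name the mm9 build, STAR 2.5.4b and Bowtie, without the role of either aligner. The Bowtie version and the filters on reads were not given in the sources used here. The Pol II files held both mates of each pair, as equal numbers of reads on both strands except for 1 unpaired read in shLsd1 replicate 2. The input file held reads of 149 bp that were not paired, no reads on unplaced chromosome pieces and no gapped alignments, so the authors' processing of the input differed from that of the Pol II libraries.

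The files held 21894346 reads for NT, 18953720 for shLsd1 replicate 1, 36568491 for shLsd1 replicate 2 and 18362687 for the input. Reads on the 19 autosomes, X and Y were analysed, between 99.3% and 99.8% of each library. The 5′ end of each read was moved 100 bp downstream and counted. Between 10.7% and 14.9% of reads shared their position and strand with another read.

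Enriched regions were built from 500 bp windows where the 3 Pol II libraries, at equal weight after scaling to library size, reached at least 4 times the input and held at least 30 reads in all. The input of a window was taken as at least its genome mean of 3.47 reads, a detail added after the files were seen. Windows were joined over gaps of 1 kb. The summit of a region was its 100 bp bin with the most reads over the 3 libraries. The focus of Pol II was the read density in 600 bp about the summit over that in the rest of the region with 3 kb on either side. The background of each library was its median count in 10 kb bins away from regions with at least 20 input reads.

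Counts of reads per region were tested with limma 3.58.1 in R 4.3.3, with voom weights, a pseudocount of 0.5, scaling by trimmed means (TMM) and Benjamini-Hochberg adjustment at 0.05. The TMM factors were computed with a written-out version of the published formula. The quasi-likelihood count test foreseen before the data were examined was replaced by limma. Such count tests were kept for deposited count tables, by choice, although the reads counted per region would have allowed one. The fit left 1 residual degree of freedom, pooled over regions. It assumed that the lone NT library varied like the shLsd1 libraries. The labels do not say whether the shLsd1 replicates were separate cultures, so p-values may measure technical spread alone. The focus was tested as the interaction of window and group with library as a block.

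Counts were simulated for 7273 regions at a dispersion of 0.05, which was assumed and not estimated from these libraries. In each draw 200 regions were changed, fewer than the 541 called in the data. The adjustment is stricter when fewer regions change, so recovery in the data may differ. The test of region counts recovered 3.33% of regions changed by 2-fold and 49.3% of those changed by 4-fold. It called 0.0566% of unchanged regions. The test of focus recovered 1.67% and 24.0% for the same folds, and called 0.0236% of unchanged regions. Shares of reads carry exact Clopper-Pearson 95% binomial intervals computed on fragments for the Pol II libraries. They cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

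Named regions were the 10 with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05 and both shLsd1 libraries on the same side of NT. Where fewer than 10 passed, the list was filled by size among regions with a mean of at least 100 reads. The design, this rule and most alternatives were fixed before the data were examined. Alternatives covered scaling, low counts, repeated positions, depth, read shift, replicates, background and the region threshold. Added afterwards were 1 read per fragment, no floor on the input, other choices of regions, each library's own background, evening out a step in shLsd1 replicate 2, a trend in place of voom weights and TMM scaling of the median change.

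An annotation of mm9 was not used here. The planned comparisons of promoters, gene bodies, pausing index and gene sets were therefore not run, and regions are given by mm9 coordinates without genes. The level of Kdm1a itself was not analysed here.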

Results

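The study asked how LSD1 bears on the pausing of Pol II, the halt of the enzyme shortly after it starts a transcript. Pol II occupancy was profiled in mouse embryonic stem cells with a non-targeting hairpin (1 library, 10947173 fragments) or with a hairpin against Lsd1 (2 libraries, 9476860 and 18284246 fragments). An input library of 18362687 reads gave the background. The 3 Pol II libraries together marked 7273 enriched regions covering 8.55 Mb of the mm9 genome on 20 chromosomes. Of these regions, 4833 were a single 500 bp window and 1186 reached 2 kb.

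The first comparison asked how much of each library lay in enriched regions. These regions held 3.30% of NT reads (95% interval 3.29 to 3.31), 1.88% of reads in shLsd1 replicate 1 (1.87 to 1.88) and 1.37% in shLsd1 replicate 2 (1.37 to 1.38). The input had 0.321% of its reads there (0.318 to 0.323). The gap between the shLsd1 replicates was itself wider than the counting error. With 1 NT library the difference from NT has no replicate check on the NT side. Its size also depends on the choice of regions. With each library's background subtracted, NT, replicate 1 and replicate 2 had 3.01%, 1.54% and 1.03% of reads in these regions. In regions chosen on both shLsd1 libraries they had 1.61%, 1.15% and 0.762%. Shares by promoter and gene body were not analysed here.

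**Figure D1:**
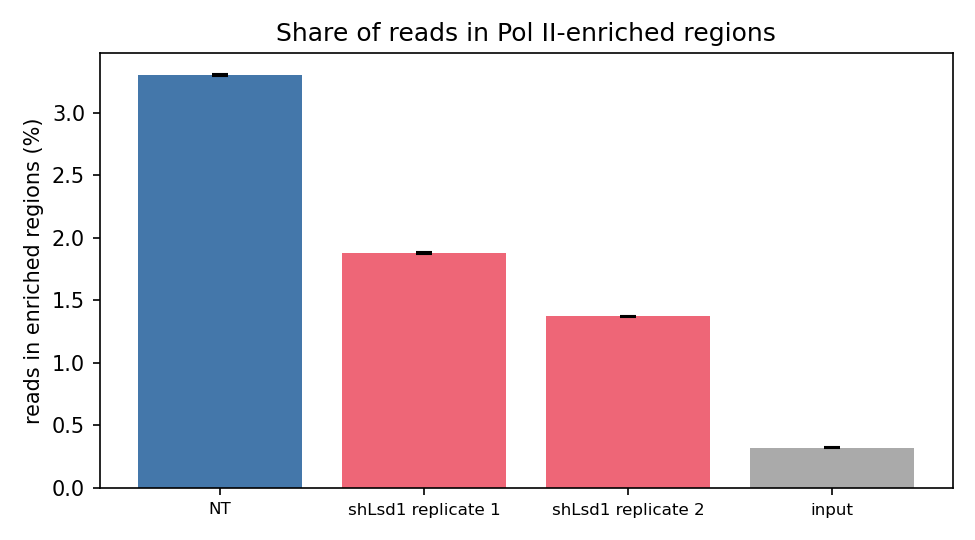
Share of reads in Pol II-enriched regions, in percent, for each of the 4 libraries; bars are single libraries and error bars are exact 95% binomial intervals. NT stands at 3.30%, the shLsd1 libraries at 1.88% and 1.37%, and the input at 0.321%.

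The second comparison set reads per region in shLsd1 cells against NT. Scaled to library size as reads per 1000000 (RPM), most of these regions held fewer reads in the shLsd1 libraries than in NT. RPM gives a share of each library and not an amount of Pol II. A difference in the efficiency of the immunoprecipitation would change it too. The median log2 change was -0.87 in shLsd1 replicate 1 and -1.35 in shLsd1 replicate 2, a mean of -1.11 ± 0.34 (SD, n = 2). Both values rest on the same NT library, so their agreement is no separate check. The fall was of like size in narrow and wide regions, with medians of -0.86 and -1.36 in single windows and -0.88 and -1.32 in regions of 5 kb or more. The regions were chosen over all libraries, and in 4365 regions chosen on the shLsd1 libraries alone the median change was -0.06 in replicate 1 and -0.61 in replicate 2, a mean of -0.34.

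Relative to the typical region, limma with TMM scaling called 312 regions higher and 229 lower in shLsd1 cells, and 1628 had an unadjusted p under 0.05. Scaled by library size the same test called 8 regions higher and 3791 lower, and with TMM over 10 kb bins 4 higher and 3979 lower. The choice of regions moved the counts too: regions chosen on the shLsd1 libraries gave 156 and 420, no floor on the input gave 99 and 1852, and leaving out regions with raised surroundings gave 166 and 89. A trend in place of voom weights gave 66 lower. Without the minimum count and the enrichment over input, mostly background DNA was tested, 74 stretches were called higher and 1778 lower, and the median log2 change in RPM turned to 0.21. The calls under the main scaling thus rank regions by how they moved against a common fall in RPM. In the paragraphs that follow, higher and lower are meant in this relative sense unless RPM is named.

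**Figure D2:**
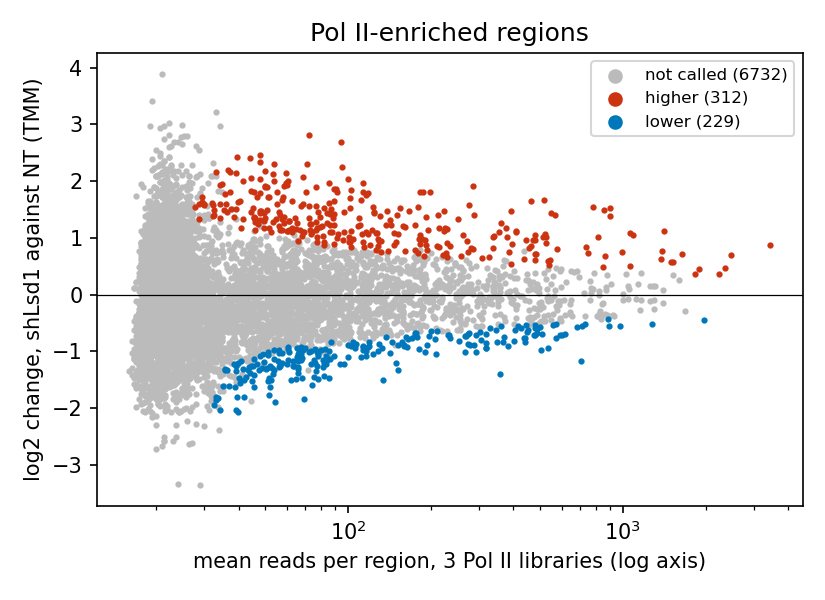
Log2 change of each enriched region in shLsd1 against NT after TMM scaling (vertical axis) by mean reads over the 3 Pol II libraries (horizontal log axis); each point is a region. Red points are the 312 regions called higher and blue points the 229 called lower at an adjusted p under 0.05.

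Regions called higher were unevenly spread over the chromosomes. Chromosomes 13 and 14 held 59 each, 37.8% of all higher calls, among 330 and 323 regions. The odds ratio was 5.76 for chromosome 13 (Fisher's exact test, two-sided, adjusted p = 5.24e-21 over 20 chromosomes) and 5.92 for chromosome 14 (adjusted p = 3.36e-21). Chromosome 8 held 38 (odds ratio 2.43, adjusted p = 3.7e-05). Of the 8 chromosomes that passed, the other 5 held fewer higher calls than expected, with the lowest odds ratio, 0.198, on chromosome 7 (adjusted p = 3.7e-05). For regions called lower, 0 of the 20 chromosomes passed by Fisher's exact test, and the smallest adjusted p was 0.257 on chromosome 12. Neighbouring regions are not independent, so these p-values are too small. Some of the clusters described below had a replicate ratio nearer to that of background DNA than to that of regions not called. Of the 59 higher calls on each chromosome, 55 on chromosome 14 and 28 on chromosome 13 sat in such clusters.

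On chromosome 13, 2 clusters of higher calls stood between 21.8 and 23.9 Mb. The first, from 21807001 to 22136500, held 9 called regions with 4026 reads in NT, 4775 in shLsd1 replicate 1 and 4885 in shLsd1 replicate 2. The second, from 23634501 to 23856500, held 14 called regions with 7229, 8715 and 9881 reads. Together they had 517 RPM in NT, 717 in shLsd1 replicate 1, 406 in shLsd1 replicate 2 and 20.6 in the input. In RPM, then, replicate 1 lay above NT (log2 0.47) and replicate 2 below it (-0.35), against medians of -0.87 and -1.35 over all regions. Of the 23 called regions, 23 exceeded NT in RPM in replicate 1 and 3 did in replicate 2. The strongest single region there by p-value, from 23830001 to 23832500, had a relative log2 change of 1.54 (SE 0.14, limma adjusted p = 5.81e-05). The region from 23713001 to 23714500 had 1.67 (SE 0.18). These clusters were picked out after their values were seen.

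**Figure D3:**
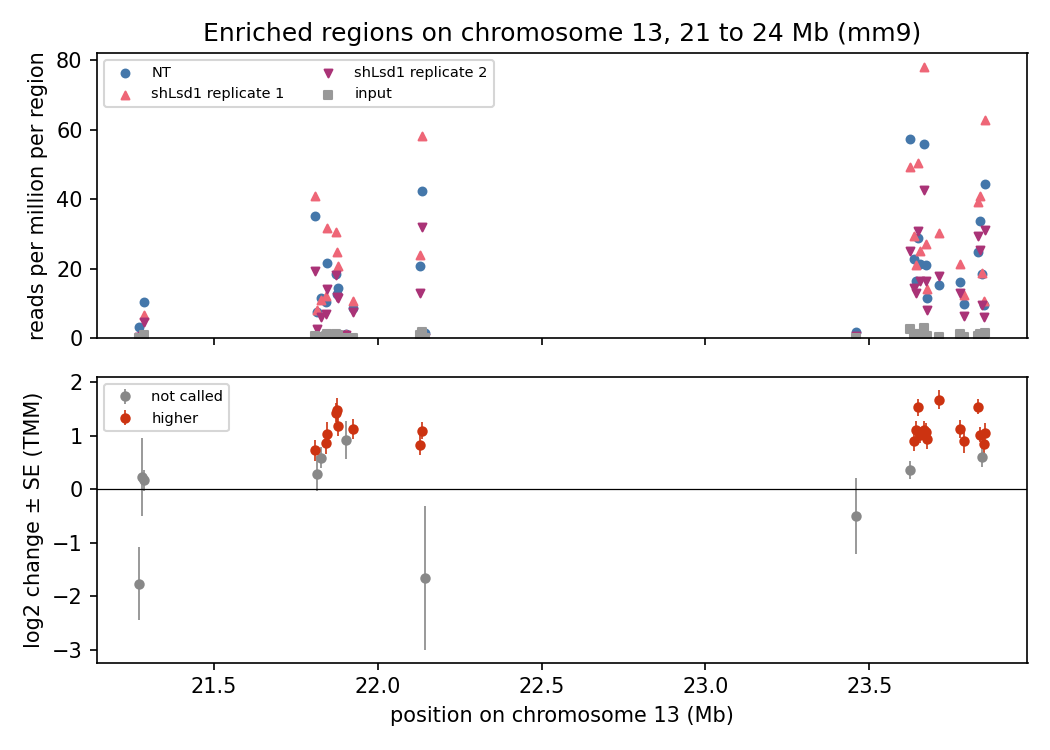
Enriched regions on chromosome 13 between 21 and 24 Mb in mm9: RPM in each of the 4 libraries (upper panel) and log2 change in shLsd1 against NT with its SE (lower panel). Of the 33 regions shown, 23 were called higher and 0 lower.

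Further higher calls came in clusters elsewhere. In all, 15 clusters of at least 5 higher calls, joined within 500 kb, held 175 regions, 56.1% of the higher calls. In 12 of them the ratio of replicate 2 to replicate 1 lay nearer to that of background DNA than to that of regions not called. The cluster on chromosome 8 from 19697501 to 20038000 held 30 called regions, with 614 RPM in NT, 569 and 491 in the shLsd1 replicates and 89.4 in the input. The cluster on chromosome 14 from 7225501 to 8345500 held 16, with 33.3 RPM in NT, 49.5 and 51.7 in the shLsd1 replicates and 4.8 in the input. Those 16 were among 45 regions in its span, and the DNA around them was raised over the input by a median of 1.62 (log2). The input in the called regions had 0.51 times its background density there, against 2.10 times in the chromosome 8 cluster. A low input makes the enrichment over input look larger. Outside clusters, the region on chromosome 3 from 96361501 to 96367000 had 27.6 RPM in NT and 40.6 and 32.7 in the shLsd1 replicates (relative log2 1.50, SE 0.14, limma adjusted p = 5.81e-05). The region on chromosome 11 from 115881001 to 115886000 had 31.2 in NT and 47.1 and 31.2 in the shLsd1 replicates (relative log2 1.38, SE 0.14). These regions were picked out after their values were seen.

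By the rule fixed beforehand, the 10 largest rises had relative log2 changes from 2.19 to 2.81, with SE from 0.32 to 0.64. They were thinly covered, with 16 to 43 reads in NT. Of the 10, 4 lay in clusters whose replicate ratio was nearer to background DNA than to regions not called. The largest was on chromosome 12 from 3014001 to 3015500, with 22 reads in NT and 49 and 145 in the shLsd1 replicates (limma adjusted p = 0.00302). It lay in a stretch, 3 to 4 Mb, where the input piled up to 1746 RPM against 647 in NT, and the DNA around it was raised over the input by 2.16 (log2). The region on chromosome 18 from 35021001 to 35022500 followed, with 33, 93 and 157 reads (log2 2.70, limma adjusted p = 0.00029). The others lay on chromosome 5 from 113936001 to 113936500 and from 15217501 to 15218000, on chromosome 15 from 13062001 to 13062500, and on chromosome 14 from 7779001 to 7780000 and from 8084001 to 8084500. The last of the 10 lay on chromosome 4 from 61220501 to 61222000, on chromosome 1 from 162971001 to 162972500 and on chromosome 8 from 81076001 to 81076500. The chromosome 1 region changed by 0.042 and was not called when windows were joined over 3 kb, and the chromosome 4 region changed by 0.75 and was not called with no floor on the input. Among the rises outside those clusters, only that on chromosome 18 had less RPM in replicate 2 (4.32) than in replicate 1 (4.94). On chromosome 15, for example, replicate 1 had 2.02 and replicate 2 had 2.09. The median log2 ratio of replicate 2 to replicate 1 over all regions was -0.45.

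The 10 largest falls had relative log2 changes from -2.06 to -1.80, with SE from 0.29 to 0.58. The largest was on chromosome 10 from 81111501 to 81112500, with 93 reads in NT and 12 and 14 in the shLsd1 replicates (limma adjusted p = 0.0411). The region on chromosome 7 from 51501501 to 51502500 had 158, 18 and 32 reads (log2 -1.84, limma adjusted p = 0.00179, but -0.51 and not called with windows joined over 3 kb), and that on chromosome 17 from 47875501 to 47876500 had 128, 10 and 25. The others lay on chromosome 2 from 28323501 to 28324000, on chromosome 8 from 109417501 to 109418000 and from 125748501 to 125749000, and on chromosome 4 from 151383001 to 151383500. Chromosome 11 from 69804501 to 69805000, chromosome 5 from 136254501 to 136255000 and chromosome 10 from 7512501 to 7513000 made up the rest. Several falls were far larger in replicate 2. In RPM the log2 changes in replicates 1 and 2 were -1.37 and -3.57 on chromosome 4, -1.29 and -3.40 on chromosome 5, and -1.46 and -3.44 on chromosome 11. These 3 were thinly covered. Reads in NT and replicates 1 and 2 were 67, 22 and 9 on chromosome 4, 66, 23 and 10 on chromosome 5, and 68, 21 and 10 on chromosome 11. NT thus held most of the reads by which these regions were chosen. The replicates were alike on chromosome 7 (-2.89 and -3.02) and chromosome 17 (-3.40 and -3.07). Medians over all regions were -0.87 and -1.35.

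Among regions of at least 2 kb called lower, those with the smallest adjusted p were picked out after their values were seen. On chromosome 7 from 134375501 to 134384000, NT had 1402 reads and the shLsd1 replicates 311 and 405 (relative log2 -1.16, SE 0.13, limma adjusted p = 0.000283). On chromosome 14 from 64116501 to 64123000 the counts were 747, 176 and 152 (relative log2 -1.40, SE 0.21, limma adjusted p = 0.00133). One cluster of lower calls, on chromosome 6 from 124424501 to 125142500, held 6 called regions with 84.4 RPM in NT and 26.7 and 17.9 in the shLsd1 replicates.

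The third comparison asked whether Pol II was more or less focused at the summit of its regions, against the rest of the region and 3 kb on either side. It does not stand for a pausing index, since in the 4833 regions of a single window the surroundings are almost all flank and the value is signal over local background. The summit was a median of 2.36 times as dense as its surroundings in NT, 2.15 times in shLsd1 replicate 1 and 1.82 times in shLsd1 replicate 2. The median log2 change of focus was -0.11 in replicate 1 and -0.35 in replicate 2, a mean of -0.23 ± 0.17 (SD, n = 2). With the input subtracted the mean turned to 0.37, and in the 162 regions with a mean of at least 100 reads in both windows it was 0.11. No direction common to all regions can therefore be given for the focus.

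Of 7271 regions tested for focus, limma called 1 higher and 1 lower, and 678 had an unadjusted p under 0.05, 75 of them higher and 603 lower. The region on chromosome 3 from 96132001 to 96134000 was called higher, with a summit 16.5 times as dense as its surroundings in NT and 32.7 and 25.3 times in the shLsd1 replicates (log2 0.76, SE 0.17, limma adjusted p = 0.0308). The region on chromosome 6 from 83456501 to 83457000 was called lower, from 7.25 times in NT to 1.82 and 0.186 times (log2 -3.33, SE 0.65, limma adjusted p = 0.00189), on 84, 10 and 2 summit reads. That region is a single window, so its value restates a loss of reads over the flanks, from 78 in NT to 7 and 2, and not a change of shape. With 1 read per position, or 1 read per fragment, 0 regions were called.

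The remaining 18 regions of the fixed list did not pass, with adjusted p from 0.124 to 0.583. The largest log2 values among them were 1.83 on chromosome 4 from 55543001 to 55545500, 1.77 on chromosome 6 from 85055501 to 85060000 and 1.76 on chromosome 15 from 78858501 to 78861500. At the other end stood -1.72 on chromosome 9 from 108466001 to 108471000, which read 0.49 when windows were joined over 3 kb. On chromosome 7 from 28115001 to 28118000 the value was -1.69, and on chromosome 11 from 74989001 to 74992500 it was -1.55.

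**Figure D4:**
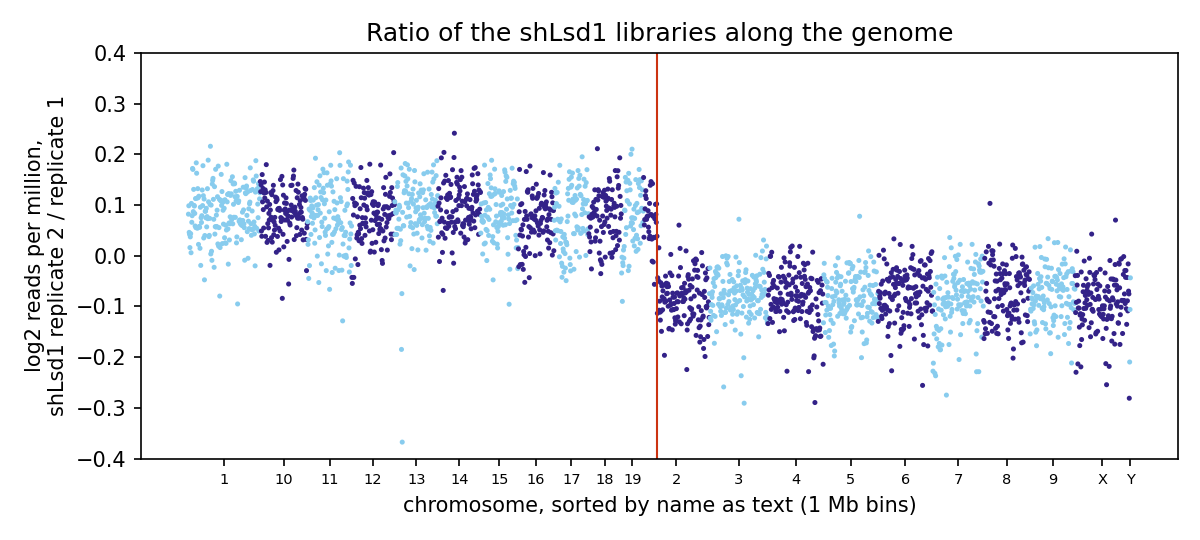
Log2 ratio of RPM in shLsd1 replicate 2 over replicate 1 in 1 Mb bins, with chromosomes sorted by name as text; each point is a bin and colours alternate by chromosome. Chromosomes before the red line at 39.66 Mb of chromosome 2 have medians from 0.07 to 0.09, and those after it, Y left out, from -0.09 to -0.07.

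Coverage of shLsd1 replicate 2 was not even along the genome. On chromosome 1, on chromosomes 10 to 19 and on chromosome 2 up to 39.66 Mb it was 1.12 times as dense against replicate 1 as on the rest. The same ratio of replicate 1 to NT was 0.989. With the step evened out, limma called 387 regions higher and 303 lower.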

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

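The tests in this part were all chosen, and their bounds set, only after the results were seen.

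Gapped alignments, reads whose 2 ends lie over 1 kb apart on the genome, were counted by their 5′ ends like other reads, but their gaps entered no comparison. The Pol II libraries held 462 distinct gaps, of which 74 appeared in all 3 libraries. The input file had 0 gapped reads, but it was processed differently and all its reads had the same length. Its 0 therefore cannot show whether the gaps are particular to the Pol II libraries. The most frequent gap, on chromosome 9 from 56108424 to 56166592, had 2 reads in NT and 10 and 15 in the shLsd1 replicates. The next, on chromosome 2 from 75501641 to 75503203, had 7, 4 and 9, and the third, on chromosome 4 from 62047121 to 62049047, had 17, 1 and 1. These are raw counts from libraries of unequal depth, and they share no direction.

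Coverage of shLsd1 replicate 2 stepped down within chromosome 2. A difference in chromosome copy number would ignore the sorted order of chromosome names. Yet the lowest chromosome before the step lay 0.14 (log2) above the highest after it. Chromosomes ranged from 0.073 to 0.094 before the step and from -0.089 to -0.070 after it. Reads missing from the later part of a sorted file would place every chromosome by its sorted position, and 19 of 19 other chromosomes (Y left out) lay on that side. A partial loss of reads in handling may therefore account for the step, and no biological explanation other than copy number was tested.

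Pol II signal in enriched regions was lower in both shLsd1 libraries. The choice of regions alone is argued against: in regions chosen on the shLsd1 libraries, the background-subtracted signal still changed by -0.49 or further, although the median region of replicate 1 changed by only -0.06. Efficiency of the immunoprecipitation cannot be told apart from the knockdown, because NT has 1 library. The gap from NT to the nearer shLsd1 library was 0.82 times the gap between the shLsd1 libraries themselves. No value of this ratio could separate the explanations with 1 NT library. An effect of the hairpin stays open and untested.

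Clusters of regions called higher could be background DNA counted as enriched, which stays open. Of 15 clusters, 12 had a replicate 2 to replicate 1 ratio nearer to background DNA (log2 0.05) than to regions not called (-0.46). Other clusters lay nearer to regions not called, and the change from NT cannot decide, because it picked the regions. The replicate ratio took no account of raised surroundings or of the input, which was processed differently. Both references were taken over the whole genome and not adjusted for the step in replicate 2. The clusters on chromosome 8 (-0.21), on chromosome 4 from 145270501 (-0.19) and on chromosome 13 from 65625001 (-0.19) lay about midway between them. Their side is therefore uncertain, and so is the count of 12. Background DNA therefore cannot be told apart from a rise in shLsd1 cells for the clusters as a set. For the 2 clusters on chromosome 13 between 21.8 and 23.9 Mb background DNA is argued against, since the higher of their ratios was -0.77.

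The 541 regions called between NT and shLsd1 compare with at most 24 when another library stood alone. Of the 3 splits, 1 reached the real count, namely the real grouping itself. In the other splits NT shared a group with a shLsd1 library, which widens the spread within that group, so 24 is no chance level. For focus the real count was 2, the highest other was 5, and 3 of 3 splits reached it, the real grouping included. The 3 splits are too few for a share under 0.05.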

How the results depend on the processing

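Alternatives added after the data were seen are those with 1 read per fragment, no floor on the input, shLsd1-chosen regions, own background, raised surroundings left out, the step evened out, a trend in place of voom weights, and TMM over regions for the median. No paired analysis was possible because NT has 1 library. The DESeq2 test was left out by choice, not run on the reads counted per region, which would have allowed it. Dropping the minimum count alone left the same 7273 regions. Dropping it together with the enrichment over input took in 90.8% of windows and gave 27074 stretches with a median of 13 kb, most of them background. The cause of each change was not tested unless named.

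Against 312 higher and 229 lower regions, median-of-ratios scaling gave 133 lower, library size 8 and 3791, TMM over 10 kb bins 4 and 3979, a mean of at least 100 reads 156 and 131 (fewer regions tested), and 8 times the input 89 and 17 (fewer regions tested). No minimum count and no enrichment gave 74 and 1778. A trend gave 66 lower, no floor 99 and 1852, shLsd1-chosen regions 156 and 420, and regions without raised surroundings 166 and 89. The median log2 change in RPM, -1.11, was -1.35 to -0.87 without either shLsd1 replicate. It became 0.012 with median-of-ratios scaling and -0.020 with TMM over regions, both of which centre it by construction, -0.38 with no floor and -0.34 in shLsd1-chosen regions. It turned to 0.21 with no minimum count and no enrichment.

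Against 1 higher and 1 lower call of focus, a mean of at least 100 reads gave 5 and 3, 1 read per position 0 and 0, thinning 3 lower, no shift 9 lower, a shift of 150 bp 3 and 5, 8 times the input 0 and 0, and no minimum count and no enrichment 0 and 0. TMM for each window gave 11 and 2, no floor 2 and 0, 1 read per fragment 0 and 0, shLsd1-chosen regions 20 and 0, and regions without raised surroundings 2 and 10. The median focus change, -0.23, was -0.35 to -0.11 without either shLsd1 replicate and -0.042 at 8 times the input. It turned to 0.25 in shLsd1-chosen regions, 0.37 with input subtracted, 0.18 with own background subtracted, 0.11 with a mean of at least 100 reads and 0.015 with TMM for each window.

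Shares of reads for NT, shLsd1 replicate 1, shLsd1 replicate 2 and input were 0.932%, 0.578%, 0.395% and 0.0439% at 8 times the input. They were 3.16%, 1.82%, 1.32% and 0.332% with 1 read per position, and 3.21%, 1.83%, 1.34% and 0.338% with no shift. For the 20 named regions, 347 of 352 alternative values kept their direction. Of the 293 with a test, 65 kept their direction but lost the call, and those that turned are counted apart. The 5 that turned did so with no minimum count and no enrichment, where each region is a small part of a longer stretch: chromosome 12 from 3014001 to -0.21, chromosome 18 from 35021001 to -0.85, chromosome 5 from 113936001 to -0.20, chromosome 1 from 162971001 to -0.51 and chromosome 8 from 81076001 to -0.36. Joining windows over 3 kb took chromosome 1 from 162971001 to 0.042 and chromosome 7 from 51501501 to -0.51, and no floor took chromosome 4 from 61220501 to 0.75, all no longer called. Of the 59 without a test 18 moved by over 1 SE, 10 of them without shLsd1 replicate 2. Without raised surroundings 3 named regions, the largest rise included, were absent and 8 of the other 17 lost the call. For the 20 regions named for focus, 279 of 290 kept it. Joining windows over 3 kb turned chromosome 2 from 29922001 to -0.44, chromosome 19 from 4798501 to -0.068, chromosome 9 from 108466001 and from 108474001 to 0.49, and chromosome 11 from 53083001 to 0.13. No minimum count and no enrichment turned chromosome 6 from 85055501 to -1.33, chromosome 2 from 29922001 to -0.97, chromosome 19 from 4798501 to -0.70, chromosome 14 from 22489501 to -0.95, and chromosome 9 from 108466001 and from 108474001 to 0.17. At this depth, with 1 NT library, an assumed dispersion of 0.05 and 200 changed regions, the simulated test missed most 2-fold changes.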

Other observations

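The tests of regions chosen on single libraries were selected after the results were seen. The NT library alone gave 7541 regions, shLsd1 replicate 1 alone 1174 and shLsd1 replicate 2 alone 4043. In regions chosen on NT, the background-subtracted share of reads was 3.54% in NT, 1.40% in shLsd1 replicate 1 and 0.945% in shLsd1 replicate 2. In regions chosen on replicate 1 it was 0.884%, 0.656% and 0.392%, and in regions chosen on replicate 2 it was 1.23%, 0.789% and 0.726%. NT was the highest of the 3 libraries under each of these choices. The median region chosen on replicate 2 alone nevertheless had a log2 change of 0.08 in that library.

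The median background bin stood higher in the shLsd1 libraries than in NT. The median 10 kb bin away from regions held 3.40 RPM in NT, 3.88 in shLsd1 replicate 1, 4.02 in shLsd1 replicate 2 and 3.98 in the input. Enriched regions held 3.30% of NT reads and 1.88% and 1.37% of shLsd1 reads. That difference is too small to move the median bin this far, so the libraries also differed outside enriched regions. The difference was not even along the genome. In 1 Mb bins, which took in enriched regions, the ratio of replicate 1 to NT took both signs. For example, its log2 was -0.78 at 80 Mb of chromosome 10 and 0.55 at 7 Mb of chromosome 12. The cause of this unevenness was not tested.

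The input held more reads than the Pol II libraries in some stretches. Between 98 and 99 Mb of chromosome 2 it had 10002 RPM, against 517 in NT and 664 and 693 in the shLsd1 replicates. Between 3 and 4 Mb of chromosome 9 it had 1602 against 442 in NT, and between 3 and 4 Mb of chromosome 12, where the largest named rise lay, 1746 against 647.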
